A study of Drosophila melanogaster with 2 samples.

How the data were processed

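The samples were 2 ChIP-seq libraries of 1 group, biological replicates 2 and 3 in the labels, made from embryos of a fly line that expresses CG33557 with a C-terminal GFP. Chromatin was sheared by sonication to a stated size range of 200 to 800 bp and precipitated with an antibody against GFP, per the labels. The labels give the age as 4 to 10 h in the source name; another age field holds a number that cannot be an age in hours and was not used. The 2 libraries were numbered as separate biological replicates; with 1 group no comparison between groups, no test across samples and no pairing of samples was possible.

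The deposited text descriptions state that each library's peaks were derived from its own alignment and a single control alignment, that a further list was derived from both libraries, and that coordinates refer to genome build dm6. The reproducible list was named as passing an optimal IDR threshold, per the labels of the deposited lists. The aligner, the peak caller and their versions are not given in the sources used here. The lists are in the narrowPeak layout without a header. Their seventh field, the signal value, is a score that the authors' peak caller gave each peak, with a scale that depends on the library; it was used only to rank peaks within a list. Their ninth field was deposited as −log10 of a q-value, per the file type named in the deposited descriptions; in the reproducible list it ran from 3.44 to 3.91, and 4094 peaks shared the highest value, so it was not used for ranking. The tenth field, the summit position in bp from the peak start, was deposited by the authors and gave each peak's location. All 4479 reproducible peaks were present in the pooled list and were exactly its 4479 strongest. The pooled list and those of both replicates end at 30000 peaks, so a peak missing from them may lie below that limit. The lists give no read counts, so depth per sample is unknown and no interval for a single peak's signal could be given.

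Sequence was taken from NCBI's Release 6 assembly of Drosophila melanogaster, which is the sequence of dm6, and genes from Ensembl's annotation of the same assembly. Arms 2L, 2R, 3L, 3R, 4, X and Y were used, 137547960 bases in all. Each base had 1 class, in the order promoter (within 500 bp of an annotated start of a protein-coding gene), 5' untranslated, 3' untranslated, coding, other exon, intron and intergenic, and each peak the class of its summit. Counts per class and per arm were compared with the share of bases by exact two-sided binomial tests. A replicate match was a summit within 100 bp; for the chance level, peaks were placed at random on the arms.

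Words were searched on both strands within 50 bp of each summit and in a window of the same length centred 500 bp away on a seeded random side, and their presence was compared by an exact two-sided McNemar test over the 4479 pairs. The words were 40: the E-box CANNTG and its 10 classes, the control GTNNAC and its 10 classes, and 18 words of other factors. All hexamers were tested likewise, and words in the strongest and weakest 1119 peaks by Fisher's exact test. GC-matched flanks, added after seeing the data, were chosen 500 to 3000 bp from the summit as the window closest to the summit's GC content, at least 200 bp from any other summit. Words by peak strength were also compared by an exact stratified test over deciles of summit GC content, likewise added after seeing the data.

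Each peak was assigned to the protein-coding gene with the nearest start. A gene's territory is the DNA nearer to its starts than to any other gene's. The number of genes of a list with a peak was compared with that of genes in the same decile of territory length by an exact two-sided stratified test over 13764 genes. This test treats genes as independent, which neighbouring genes of a list are not. The 23 lists covered muscle, mesoderm, heart, blood, nervous system, trachea, epidermis, gut, germline, patterning, Notch, bHLH, heat shock, ribosomal protein, proteasome and chemoreceptor genes; 5 of their names matched no gene with a territory of its own and are not analysed here. Adjusted p-values are by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Intervals are 95% Wilson intervals.

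The lists, the words, the tests and most alternatives were fixed before the data were examined. So was the rule for named items: CG33557; the nearest genes of the 20 strongest peaks; the 10 genes with the most peaks, which ties made 12; members from among the 4 with the highest signal in each list with more genes than expected; and the 10 hexamers with the largest ratio among those past the threshold and present at 2% or more of summits. Alternatives were the stronger part of the list, each replicate's own 4479 strongest peaks in place of the reproducible list (leaving out the other replicate), other windows, distances and flanks, peaks outside promoters, other distance limits for genes, Fisher's test without strata, and another background.

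The steps were tested on simulated data. With 4479 random positions, no annotation class of 7 was called and 1 of 40 words was called. With CAGCTG placed at 5% of them, that word was called with a ratio of 2.16 and had the lowest p among hexamers, and 1 word not matching it was also called. In 50 draws each of 13764 genes was given a peak with a chance set by its territory length, and none of 1150 list tests was called. With 70% of a list of 20 genes given a peak, the list was called in 48 of 50 draws. The simulated data were built with neither a GC difference between summits and flanks nor clusters of neighbouring genes with peaks. The gene draws followed territory length, the quantity used for the strata. They did not copy the concentration of real peaks near starts, so they could not show an error from it. Other planted lists and shares were not tried. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and, for the plots, matplotlib 3.10.9 were used.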

Results

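The data came from chromatin immunoprecipitation sequencing (ChIP-seq) of whole Drosophila melanogaster embryos, 4 to 10 h old and of mixed sex, from a transgenic fly line. The line carries CG33557, a gene for a basic helix-loop-helix (bHLH) protein, fused at its C-terminal end to green fluorescent protein (GFP), and an antibody against GFP recovered the tagged protein with its DNA. The series held 2 libraries, biological replicates 2 and 3 of a single group, with no second condition to compare. The questions it can answer are where the antibody recovered DNA and how alike the libraries were. Neither library came from untagged embryos, so whether a peak depends on the tagged protein was not tested. The deposited lists were 4479 peaks passing a reproducibility threshold (the irreproducible discovery rate, IDR), 30000 peaks called on both libraries together, and 30000 peaks for each library alone. The lists hold no read counts, so the sequencing depth behind each value is unknown. The 4479 reproducible peaks, which formed 4284 separate regions with a median peak width of 424 bp, were used throughout unless another list is named.

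Each library's own list held nearly all of the reproducible peaks. This match was largely fixed in advance, since these were the 4479 strongest peaks called on both libraries together. Of the 4479 peaks, 96.2% had a summit within 100 bp in replicate 2's own list (95% Wilson interval 95.7 to 96.8%), and 97.8% had a summit within 100 bp in replicate 3's own list (97.4 to 98.2%). In total 4220 peaks (94.2%) were matched in both libraries and 6 in neither. The median distance between summits was 17 bp for replicate 2 and 4 bp for replicate 3. When equally long lists of each library's 4479 strongest peaks, chosen without regard to agreement, were set against each other, 3217 peaks (71.8%, interval 70.5 to 73.1%) were matched, against 0.690% after random placement. The share was 85.0% among the 500 strongest peaks and 43.3% among all 30000, where random placement gave 4.47%.

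**Figure D1:**
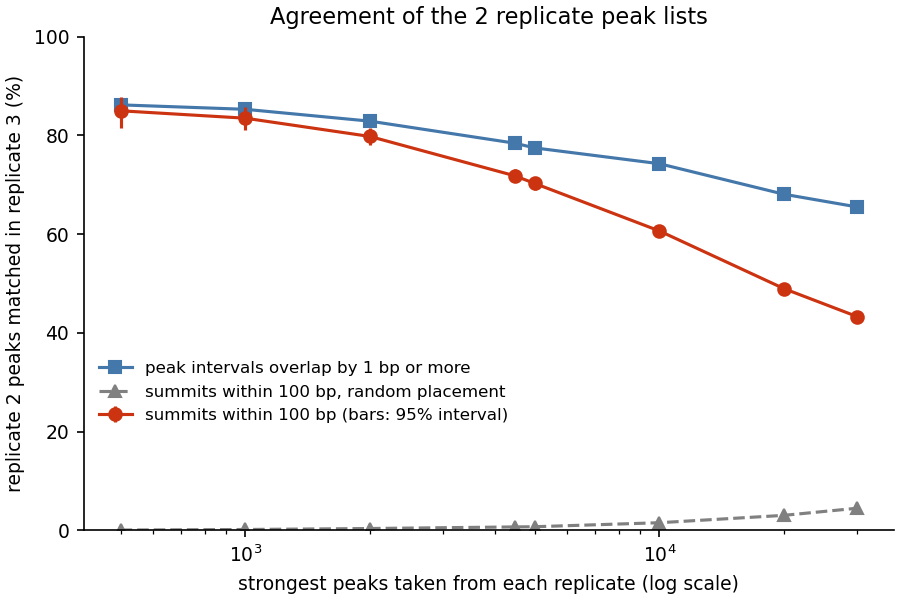
Share of replicate 2's strongest peaks matched in an equally long list from replicate 3 (y axis, %) against list length (x axis, log scale); red circles show summits within 100 bp with 95% intervals, blue squares overlapping intervals, grey triangles random placement. The share within 100 bp falls from 85.0% for 500 peaks to 43.3% for 30000 peaks and lies above random placement at every length drawn.

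The strongest peak lay on arm 3L at 19590413 to 19590845, 93 bp from the start of CG14100, with a signal value of 4007. It was followed by peaks in the promoters of px, a gene of wing vein patterning (2R, 22514068 to 22514528, signal 3741), and Art3, which encodes an arginine methyltransferase (3R, 15229321 to 15229744, signal 3559). The fourth strongest peak lay in an exon of a non-coding transcript, lncRNA:CR31840, 2911 bp from the start of hll, and the fifth in an intron of sbb, a transcriptional corepressor gene (2R, 18336832 to 18337479). Genes of chromatin regulators stood among the 20 strongest peaks. The Polycomb group genes ph-p (signal 3135, promoter) and Psc (2583, 4227 bp from its start) were among them, as was Trl, which encodes the GAGA factor (2133, intron). The remaining nearest genes were CG1888, Fkbp14, CG11050, CG18549, Pal1, CG18428, the cyclin gene CycB, the elongation factor gene eEF1gamma, the kinase genes Tlk and Lk6, the Notch target E(spl)m7-HLH, and cbt, whose peak lay in an intron of ush. Of these 20 summits 10 were in promoters, 6 in introns, 3 in intergenic DNA and 1 in another exon; 5 held an E-box within 50 bp. All 20 were among the 21 strongest peaks of replicate 2's own list and the 23 strongest of replicate 3's. The signal value is the authors' own and was used only to order peaks within a list.

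Of 13764 protein-coding genes tested, 2899 (21.1%) were the nearest gene to at least 1 peak, and 2125 of these had a single peak. Eip75B, which encodes an ecdysone-induced nuclear receptor, collected 19 peaks, where its share of the genome would give 3.65. The Hox cofactor gene hth and the Wnt receptor gene fz2 had 11 each. With 10 peaks each came the Ets factor gene pnt, px, the zinc finger gene shn, the forkhead gene CHES-1-like and tara. With 9 each came CG6163, bun, cic and pyd. Replicate 2's own list gave Eip75B 17 peaks and replicate 3's gave 17. The other 11 genes had 7 to 13 peaks in replicate 2's list and 8 to 11 in replicate 3's. These counts were not tested against length.

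Peaks lay at promoters more often than any other class, and almost never in coding sequence beyond the promoter window. Within 500 bp of an annotated start of a protein-coding gene lay 2145 summits, or 47.9% (interval 46.4 to 49.4%), against 11.2% of bases, a ratio of 4.28. Only 11 summits (0.246%) fell in coding sequence beyond the promoter window and untranslated regions, a class with 13% of bases (exact binomial test, adjusted p = 4.06e-248). In 3' untranslated regions beyond the promoter window lay 31 (0.692%), against 5.04% of bases (adjusted exact p = 5.22e-61). Introns held 32.6% of summits against 39.5% of bases (adjusted exact p = 1.80e-21), and intergenic DNA 15.7% against 29.0% (adjusted p = 1.04e-95). Exons outside coding sequence and untranslated regions held 2.17% against 1.44% (adjusted exact p = 1.41e-04), and 5' untranslated regions beyond the promoter window did not pass the test (0.692% against 0.774%, adjusted p = 0.609). The promoter share was 48.7% in replicate 2's own list and 48% in replicate 3's. Peaks are not replicates, so p-values and intervals over peaks cover counting error only. Set against the weaker pooled peaks in place of all bases, the excess in other exons was lost.

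**Figure D2:**
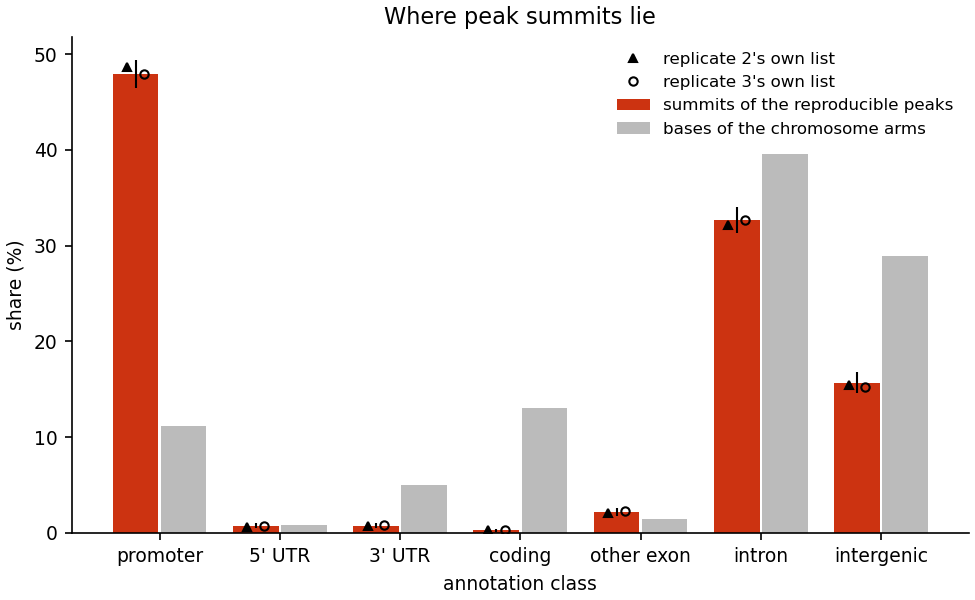
Share of the 4479 reproducible summits (red bars, with 95% Wilson intervals) and of the bases of the chromosome arms (grey bars) in each annotation class (y axis, %), with each replicate's own 4479 strongest peaks as black symbols. Promoters hold 47.9% of summits and 11.2% of bases, and coding sequence beyond promoters and untranslated regions 0.246% of summits and 13% of bases.

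Arms 2L and 3L carried more peaks than their length would give, and the X chromosome fewer. Length alone was used, without regard to chromosome copy number in embryos of mixed sex or to how much of each arm can be mapped. Arm 2L held 19.3% of summits against 17.2% of bases (ratio 1.13, exact binomial test, adjusted p = 3.86e-04) and arm 3L 23.1% against 20.4% (ratio 1.13, adjusted p = 4.62e-05). The X held 15.1% against 17.1% (ratio 0.881, adjusted exact p = 4.59e-04). Arms 2R and 3R and chromosome 4 did not pass the test (adjusted exact p = 0.318, 0.332 and 0.112). No peak lay on the Y, which has 2.49% of bases; a count of 0 among 4479 peaks allows a share of up to 0.0670%. Against the weaker pooled peaks in place of bases, arms 2L and 3L did not pass the test (adjusted exact p = 0.339 and 0.111) and chromosome 4 stood below its share (ratio 0.549, adjusted p = 4.27e-04).

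The E-box CANNTG, the class of word that bHLH proteins bind, was less frequent at summits than in the DNA beside them. It stood within 50 bp of 1531 summits (34.2%, interval 32.8 to 35.6%) and in 1872 windows centred 500 bp from the same summits (41.8%, 40.4 to 43.2%), a ratio of 0.818 (exact McNemar test, adjusted p = 1.19e-12). Replicate 2's own list gave a ratio of 0.841 and replicate 3's 0.887. Of the 10 E-box classes, CACCTG (ratio 0.560), CAACTG (0.723), CACATG (0.730), CAAGTG (0.784) and CAATTG (0.787) were rarer at summits, with adjusted p between 1.12e-06 and 0.0368. CATATG was more frequent (4.33% against 3.26%, ratio 1.33, adjusted exact p = 0.0216), and the remaining 4 classes, CAAATG, CACGTG, CAGATG and CAGCTG, did not pass the test. Summit windows were also poorer in G and C than flanks, at 34.7% against 43.5%, and against flanks of the same locus matched on GC content, an alternative chosen after seeing the data, the CANNTG ratio was 0.963 (adjusted exact p = 0.334) and no class passed the test.

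Words of other factors did stand out at summits. The Fox word TRTTTAC, bound by forkhead proteins, had the lowest p and was found at 554 summits (12.4%, interval 11.4 to 13.4%) and in 215 flanks (4.80%, 4.21 to 5.47%), a ratio of 2.58 (exact McNemar test, adjusted p = 1.48e-36). The DNA replication-related element TATCGATA (DRE), a word of housekeeping promoters, was at 81 summits and in 8 flanks (1.81% against 0.179%, ratio 10.1, adjusted exact p = 2.52e-15), and the M1BP word GGTCACAC, another promoter word, at 41 and 11 (ratio 3.73, adjusted p = 7.95e-05). The DRE ratio rests on few flanks and moved to 15.3 in replicate 2's own list, 4.17 in replicate 3's and 3.30 among the stronger 2239 peaks, where the M1BP word did not pass the test (adjusted exact p = 0.314). DRE was not centred on summits. It stood at 0.223 words per kb at the summit, 0.223 at 100 bp to one side and 0.196 at 100 bp to the other. The Mef2 word YTAWWWWTAR (7.32% against 2.88%, ratio 2.54), the homeodomain word TAATTA (ratio 1.70) and the GATA word WGATAA (17.3% against 10.6%, ratio 1.63) were also more frequent, with adjusted p of 1.63e-20, 7.73e-12 and 2.63e-19. The words of Zelda (ratio 0.341, adjusted exact p = 4.74e-04), Runx (0.576, adjusted p = 6.91e-04) and TEAD (0.708, adjusted p = 0.0368) were rarer. The 9 other words, those of the GAGA factor, NK homeodomain, Ets, Su(H), T-box, Grainyhead, AP-1 and Tramtrack proteins and the CA repeat, did not pass the test.

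Against GC-matched flanks the Fox word (ratio 1.90, adjusted exact p = 3.17e-19), DRE (4.26, adjusted p = 3.32e-09), M1BP word (2.56, adjusted p = 5.62e-03) and Mef2 word (1.23, adjusted p = 0.0271) stayed more frequent at summits. With summit and matched flank also outside coding sequence, the M1BP and Mef2 words no longer passed the test (both with an adjusted exact p = 0.0594). The GATA word (1.09, adjusted exact p = 0.152) and the homeodomain word (0.995, adjusted p = 1) no longer passed the test. The Ets word CCGGAAR (2.07, adjusted exact p = 3.22e-04) and the GAGA word (1.59, adjusted p = 0.0234) became more frequent at summits against GC-matched flanks, though the GAGA word did not pass the test with both windows outside coding sequence (1.25, adjusted p = 0.347). Of the words rarer at summits, that of Runx stayed so (0.648, adjusted exact p = 0.0218), while those of Zelda and TEAD no longer passed the test. GTNNAC, a word with the letters of the E-box in another order, served as a control. Against flanks 500 bp away it was itself more frequent at summits (26.4% against 22.3%, ratio 1.18, adjusted exact p = 3.71e-05). Its form GTAAAC, at 8.46% against 4.71%, is part of the Fox word. The forms GTACAC (ratio 1.76), GTATAC (1.80) and GTGCAC (1.43) also passed as more frequent, and GTAGAC (0.633) and GTCCAC (0.441) as rarer. Outside promoters the Fox word had a ratio of 3.38 (14.8% of 2334 summits), while DRE stood at 0.214% of summits and of flanks alike.

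**Figure D3:**
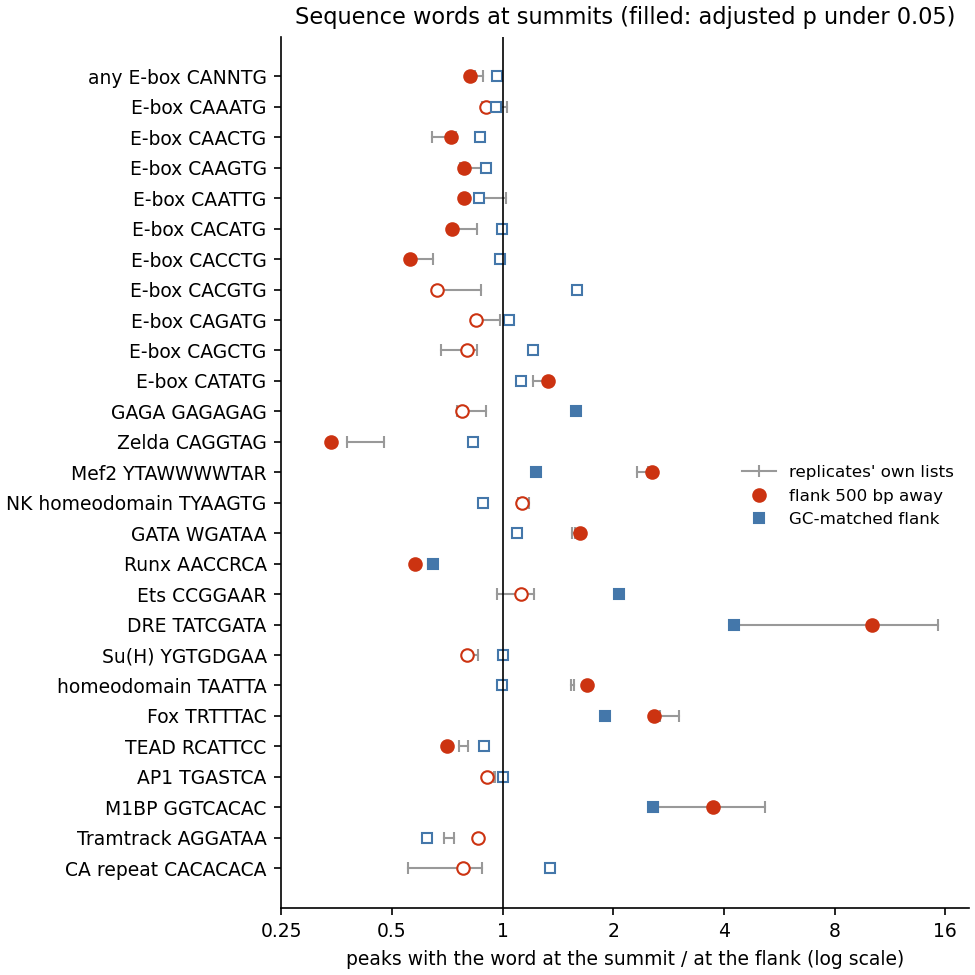
Ratio of the peaks with a word at the summit to those with it in the flank (x axis, log scale) for each E-box class and each other word found in at least 50 summit and flank windows together (y axis); red circles use the flank 500 bp away, blue squares GC-matched flanks, grey bars span both replicates' own lists, and filled symbols have an adjusted p under 0.05. Any E-box lies at 0.818 and 0.963, the Fox word at 2.58 and 1.90, and DRE at 10.1 and 4.26.

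**Figure D4:**
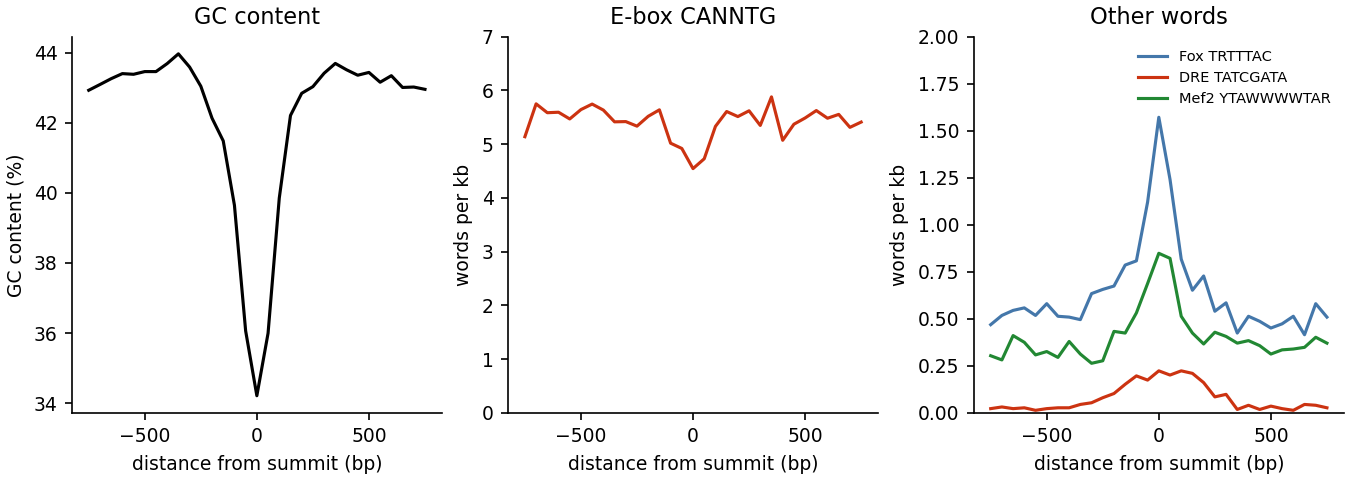
Mean GC content (left, %) and words per kb for the E-box (middle) and the Fox, DRE and Mef2 words (right) in bins around the 4479 summits (x axes, distance in bp). GC content and the E-box dip at the summit, while the Fox and Mef2 words are highest there. DRE is raised over a broader stretch, at 0.223 words per kb at 0 bp, 0.223 at 100 bp and 0.210 at 150 bp.

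Among all hexamers joined with their reverse complements, 406 were more frequent at summits and 934 less frequent (exact McNemar test, adjusted over all). Of the 10 with the largest ratios, AATATT (18.9% against 7.21%, ratio 2.62), ATATTA (2.56), TTATAA (2.40), AAATAT (2.28), TAAATA (2.28), TATTAA (2.25) and TTTAAA (2.24) contain A and T alone. The others were TAGCTA (2.48), TACTAA (2.23) and CGATAG (4.78% against 1.99%, ratio 2.40, adjusted exact p = 3.39e-12), which overlaps the core of DRE by 5 bases. Against GC-matched flanks 84 hexamers were more frequent and 86 less frequent; CGATAG then had a ratio of 2.33 (adjusted exact p = 1.48e-09), and the A and T hexamers ratios of 1.10 to 1.34.

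The 1119 strongest and the 1119 weakest peaks held any E-box in 32.0% and 35.9%, a difference that did not pass the test (Fisher's exact test, adjusted p = 0.151). CAGCTG was rarer in the strongest (2.06% against 5.18%, adjusted exact p = 1.05e-03), as was CAGATG (1.79% against 3.66%, adjusted p = 0.0489). The Mef2 word (10.2% against 5.72%, adjusted exact p = 2.13e-03), the homeodomain word (11.6% against 7.42%, adjusted p = 5.32e-03) and the Fox word (14.6% against 10.7%, adjusted p = 0.0168) were more frequent in the strongest. DRE (1.07% against 2.68%, adjusted exact p = 0.0168) and the M1BP word (0.268% against 1.34%, adjusted p = 0.0168) were less frequent there, as were the words of Su(H) (0.447% against 2.06%), the GAGA factor and the CA repeat; the promoter share was 46.7% against 48.7% (p = 0.374). In each replicate's own list E-boxes were rarer in the strongest peaks, by 6.88 percentage points in replicate 2 (adjusted exact p = 8.26e-03) and 8.22 in replicate 3 (adjusted p = 2.31e-04). The summits of the strongest peaks were also poorer in G and C than those of the weakest (30.8% against 37.8%), and within deciles of GC content, a test added after seeing the data, only the Fox word still passed, at 163 of the strongest peaks against 138 expected (exact stratified test, adjusted p = 0.0141).

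Ribosomal protein genes were the group with the clearest excess of peaks. A peak was assigned to 69 of 85 (81.2%), where genes of like territory length would give 14.9 (ratio 4.62, exact stratified test, adjusted p = 7.37e-38). For all 69 the strongest assigned peak lay in the promoter, at a median of 30 bp from the start, and its median signal value was 339, against 233 for promoter peaks as a whole. RpS27 (3R, summit 25247488, signal 972), RpL7 (2L, 10201035, 843) and RpL34b (3R, 9401342, 808) were among those with the highest values. Replicate 2's own list reached 80.0% of the 85 genes and replicate 3's 83.5%. Proteasome genes, also transcribed in most cells, carried a peak at 6 of 32 (18.8%), against 5.00 expected (adjusted exact p = 0.651).

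Genes of the Notch pathway, which acts in cell fate choice, had a peak at 14 of 20, against 4.54 expected (ratio 3.09, adjusted exact p = 3.95e-05). E(spl)m7-HLH (3R, summit 26036661, signal 2160), numb (2L, 9449662, 1262), E(spl)m3-HLH (3R, 26021384, 1079) and neur (3R, 9033929, 582) were highest, all in promoters. Several of these genes are neighbours in the E(spl) complex and are not independent. Endoderm and gut genes had a peak at 11 of 13, against 4.09 expected (ratio 2.69, adjusted exact p = 5.19e-04), led by bowl (2L, 3771506, signal 1085), the forkhead gene fkh (3R, 28585517, 765), the nuclear receptor gene Hnf4 (2L, 8691536, 641) and sob (2L, 3588503, 573). Here drm and sob on 2L, and srp and GATAe on 3R, lie close together and are not independent. With peaks counted only up to 1000 bp from a start, the endoderm list lost its call (adjusted exact p = 0.0683) at a ratio of 2.57.

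Genes of mesoderm and its tissues were also among those with more peaks. Early mesoderm genes had a peak at 13 of 19, against 6.20 expected (ratio 2.10, adjusted exact p = 6.89e-03), with stumps, an adaptor of fibroblast growth factor signalling (3R, summit 14591291, signal 1200), zfh1 (3R, 30781779, 851), tin (3R, 21378764, 744) and Traf4 (2L, 4371729, 684) highest. Cardiac genes had a peak at 12 of 19, against 5.94 (ratio 2.02, adjusted exact p = 0.0149), with zfh1, tin, the netrin receptor gene unc-5 (2R, 15349906, 685) and tup (2L, 18890280, 660) highest. Of the cardiac genes with a peak, Doc1 and Doc2, and mid and H15, lie close together and are not independent. Genes of somatic muscle identity had a peak at 13 of 23, against 7.35 (ratio 1.77, adjusted exact p = 0.0452), with org-1 (X, 8455427, 1094), tup, Poxm (3R, 8334190, 594) and caup (3L, 12606505, 587). Sarcomere genes, which encode the contractile apparatus, had a peak at 7 of 23, against 6.47 expected (adjusted exact p = 0.814). The lists of myoblast fusion (9 of 19), muscle attachment (9 of 17) and visceral muscle (4 of 9) did not pass the test. The early mesoderm call was lost among the stronger 2239 peaks (ratio 2.00, adjusted exact p = 0.0962) and with peaks counted only up to 1000 bp from a start (2.23, 0.0683). The cardiac call was lost with peaks up to 10000 bp (1.88, 0.0520), up to 1000 bp (2.01, 0.214) and in promoters with chromosome Y also left out (1.64, 0.469, 5 genes against 3.06 expected). Somatic muscle identity lost its call under those same 3 limits (ratios 1.67, 1.42 and 1.64), among the stronger 2239 peaks (1.72) and in replicate 2's own list (1.48), while muscle attachment passed the test in replicate 3's own list (0.0291).

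Patterning genes were also among those with more peaks. Segmentation genes had a peak at 14 of 22, against 7.45 expected (ratio 1.88, adjusted exact p = 0.0160), highest at slp1 (2L, summit 3827872, signal 1345), ptc (2R, 8654430, 1153), slp2 (2L, 3832522, 1028) and nkd (3L, 19042686, 848). Hox genes and cofactors had a peak at 9 of 12, against 4.36 (ratio 2.06, adjusted exact p = 0.0272), at Abd-B (3R, 16958244, 696), Antp (3R, 6903414, 492), hth (3R, 10598372, 430) and lab (3R, 6665495, 421). All 8 of these peaks lay in introns or intergenic DNA. Neural progenitor genes had a peak at 15 of 30, against 8.90 (ratio 1.69, adjusted exact p = 0.0454), highest at grh (2R, 17804951, 1010), D (3L, 14174386, 576), vnd (X, 582039, 411) and ase (X, 458018, 387), and tracheal genes at 9 of 14, against 4.87 (ratio 1.85, adjusted p = 0.0454), highest at trh (3L, 377672, 672), vvl (3L, 6824031, 540), verm (3L, 19694254, 480) and peb (X, 4609884, 393). These lists share members with each other and with the mesoderm lists. Some of their genes with a peak lie close together and are not independent, such as slp1 and slp2, en and inv, and kni and knrl. The same holds for lab, pb, Dfd and Antp, and for abd-A and Abd-B. None of the 4 lists passed the test with peaks counted only up to 1000 bp from a start. Up to 10000 bp segmentation (11 genes against 6.67 expected, adjusted exact p = 0.0911), Hox (7 against 3.80, 0.0911) and neural progenitor genes (14 against 8.14, 0.0520) lost their calls. Among the stronger 2239 peaks neural progenitor (6 against 5.50, adjusted exact p = 0.887), Hox (5 against 2.88, 0.325) and tracheal genes (7 against 3.15, 0.0581) did. With promoter peaks alone and without chromosome Y all 4 did. The neural progenitor call was also lost in each replicate's own list, the tracheal call in replicate 2's and the Hox call in replicate 3's.

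Heat shock genes had a peak at 7 of 15, against 2.69 expected (ratio 2.61, adjusted exact p = 0.0266), highest at Hsp83 (3L, summit 3193094, signal 858), Hsp27 (3L, 9383851, 368), Hsc70-4 (3R, 15242505, 212) and Hsp68 (3R, 24057448, 211). That call was lost in replicate 2's own list, with 5 of 15 genes (adjusted exact p = 0.264), and among the stronger 2239 peaks, with 2 of 15 (0.834). Of the 7 genes Hsp22, Hsp23, Hsp26 and Hsp27 are neighbours on 3L and are not independent. Chemoreceptor genes, which function in sensory neurons, were the 1 group with fewer peaks, at 6 of 177 against 37.4 expected (ratio 0.161, adjusted exact p = 6.36e-11). Genes of differentiated neurons (4 of 21, against 6.46), glia (6 of 12, against 3.11), hemocytes (5 of 15, against 3.92), epidermis and cuticle (5 of 14, against 3.89) and the germline (3 of 10, against 1.93) did not pass the test. Genes of bHLH factors had a peak at 18 of 48, against 12.3 expected (adjusted exact p = 0.0949), a list that passed the test among the stronger 2239 peaks and in replicate 3's own list (adjusted p = 0.0409 and 0.0482).

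**Figure D5:**
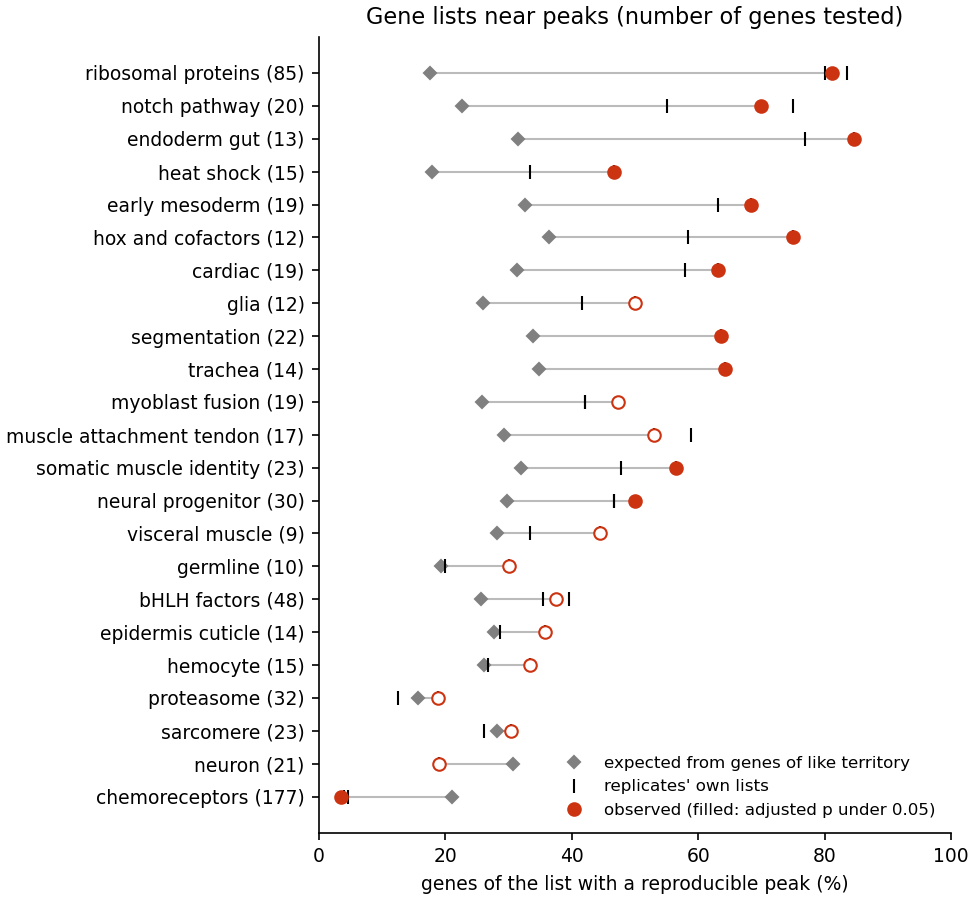
Share of the genes of each list with a reproducible peak (red circles, filled where the adjusted p is under 0.05), the share expected from genes of like territory length (grey diamonds) and the share in each replicate's own list (black ticks); x axis in %, number of genes tested in parentheses. Ribosomal protein genes lie at 81.2% against 17.6% expected and chemoreceptor genes at 3.39% against 21.1%.

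The gene whose product was tagged, CG33557, lies on the plus strand of the X chromosome at 10009210 to 10010049. No reproducible peak was assigned to it. A peak at 10010017 to 10010440 overlapped the end of the gene, with its summit at 10010229, 180 bp beyond that end and 252 bp before the start of Dna2, the neighbouring gene to which it was assigned. Its signal value of 218 ranked it 2585 of 4479. Replicate 2's own list placed the summit at 10010178 and replicate 3's at 10010224. At the start of CG33557, the pooled list held a weaker summit 255 bp upstream with a signal value of 81.1, and replicate 3's list held summits 171 bp upstream and 34 bp from the start. In replicate 2's list the summit nearest to that start lay 625 bp upstream, at rank 19935 of 30000.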

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

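A signal appeared in data outside the main comparisons, in the pooled peaks below the reproducibility threshold. Of 24272 pooled peaks that did not overlap a reproducible peak, 8342 (34.4%) had a summit within 100 bp in both replicates' own lists, against 1.82% after random placement. These 8342 peaks lay in promoters in 31.3% of cases (interval 30.3 to 32.3%), below the 47.9% of the reproducible peaks. Their summits held the Fox word at 8.75% against 4.24% of flanks (ratio 2.06, adjusted exact p = 9.32e-31) and DRE at 1.59% against 0.324% (ratio 4.93, adjusted p = 6.63e-17). The M1BP word stood at 1.40% against 0.192% (ratio 7.31, adjusted exact p = 7.60e-19). CANNTG stood at 40.0% of summits and 40.2% of flanks (adjusted exact p = 0.952). Of its classes only CAGCTG, more frequent at summits (5.32% against 4.44%, ratio 1.20, adjusted exact p = 0.0356), and CAATTG, rarer there (ratio 0.820, adjusted p = 0.0346), passed the test. Of 16 ribosomal protein genes without a reproducible peak, 11 had a peak in this part of the pooled list. The share of all genes with such a peak was not determined, so no excess can be read from this count. Because the pooled list and the replicates' lists were called on the same libraries, the match is not independent evidence of binding.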

How the results depend on the processing

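Alternatives with GC-matched flanks, pairs outside coding sequence, the strongest 1119 peaks, strata of GC content, promoter peaks and a background without chromosome Y were chosen after seeing the data; the cause of each change below was not tested. No paired analysis was possible because all samples form 1 group. The agreement of 71.8% became 78.4% with overlapping intervals, 58.1% within 50 bp, 83.5% for 1000 peaks and 70.3% for 5000 peaks. Against the weaker pooled peaks as background, the ratio of other exons turned to 0.963, that of 5' untranslated regions was 0.581 and passed the test, arms 2L (1.03) and 3L (1.05) did not, and 3R (1.11) and chromosome 4 (0.549) did. Chromosome 4 also passed among the stronger 2239 peaks (0.506).

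The CANNTG ratio missed the threshold against GC-matched flanks (0.963), those outside coding sequence (0.943) and, at 1.05, with GC-matched flanks in the strongest 1119 peaks; elsewhere it passed, from 0.781 to 0.915. The count of E-box classes higher at summits, 1, fell to 0 among the stronger 2239 and the strongest 1119 peaks and with both kinds of GC-matched flank, and ranged from 0 to 1 in single replicates. The count lower at summits, 5, fell to 2 outside promoters and to 0 with both kinds of GC-matched flank, and ranged from 2 to 5 in single replicates. Among promoter peaks only CACCTG was lower (0.438) and no class was higher. CAAGTG turned to 1.05 outside promoters, CAATTG to 1.02 in replicate 3's own list (0.863 in replicate 2's) and CACCTG to 1.16 with GC-matched flanks outside coding sequence. With GC-matched flanks GAGA turned to 1.59 and the homeodomain word to 0.995, 1 of 18 other words was lower at summits in place of 3, and 84 hexamers were higher and 86 lower. With those flanks outside coding sequence 3 other words were higher in place of 6, and 1 was lower. The difference in CANNTG between strong and weak peaks was -8.22 to -6.88 points in single replicates, past the threshold. Within deciles of GC content no E-box class passed the test by strength, and of 18 other words only the Fox word did.

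The number of lists with more genes than expected, 11, became 6 among the stronger 2239 peaks, 6 with starts within 10000 bp, 3 within 1000 bp and 5 with promoter peaks alone and chromosome Y left out, and was 7 to 11 in single replicates; with Fisher's exact test over all genes it rose to 15, with myoblast fusion, muscle attachment, glia and bHLH genes added. Within 1000 bp the ratios of segmentation (0.966) and Hox genes (0.846) turned, and that of Hox genes also with promoter peaks without chromosome Y (0.972). Calls for ribosomal protein, Notch and chemoreceptor genes held in all 7 alternatives. The lists give no counts, so what depth limits could not be examined. Over all settings, single words and lists kept their call 327 times, lost it 79 times, gained it 22 times and turned 8 times; overall results kept their call or value 125 times, moved 23 times, gained a call 6 times, lost it 4 times and turned 1 time.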

Other observations

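In this part the gene lists, the small RNA genes, the GC-matched flanks, the pairs outside coding sequence, the strongest 1119 peaks and the promoters without a peak were chosen only after the main results had been seen, and the tests on proteasome genes, on the TCT word and on DRE outside promoters were set, or in the last case given their final meaning, after their own results had been seen. The test on weak peaks replaced an earlier form without GC matching, whose ratio of 0.782 had been seen. Genes of the Polycomb and trithorax groups, which keep and release gene silencing, had a peak at 14 of 25, against 6.05 expected (exact stratified test, ratio 2.31, adjusted p = 3.74e-03). The highest were ph-p (signal 3135), Psc (2583), Trl (2133), ph-d (1594) and E(z) (1186), and 13 genes had a peak in each replicate's own list. Cell cycle genes had a peak at 9 of 19, against 3.90 (adjusted exact p = 0.0273), with CycB (2336), CycE (1253) and E2f1 (807) highest; replicate 2's own list gave 6 and replicate 3's 10. Nuclear receptor genes (11 of 20, adjusted exact p = 0.0617), translation factor genes (16 of 50, adjusted p = 0.0896), insulator protein genes (4 of 10, adjusted p = 0.162), respiratory chain genes (18 of 80, adjusted p = 0.506), mitochondrial ribosomal protein genes (12 of 73, adjusted p = 0.744, with 22 in replicate 2's own list and 8 in replicate 3's) and vacuolar ATPase genes (5 of 33, adjusted p = 0.744) did not pass the test. Because ph-p, Psc, Trl and CycB prompted these lists, their counts are not independent evidence.

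Genes of small RNAs had more summits near them than their share of bases would give. That background ignores the concentration of peaks near starts of protein-coding genes, and no comparison with other DNA near genes was made. Within 200 bp of the 32 small nuclear RNA genes were 6 summits, against 0.589 expected from their share of bases (exact binomial test, adjusted p = 1.05e-04), and both replicates' own lists gave 7. Near 290 transfer RNA genes lay 10 summits, against 3.98 (adjusted exact p = 0.0118), with 5 in replicate 2's list and 13 in replicate 3's. Near 269 small nucleolar RNA genes lay 8, against 3.31 (adjusted exact p = 0.0201), with 6 and 9.

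E-boxes were rarer at summits than in flanks, although the tagged protein is of the bHLH class. Flanks in coding sequence do not account for this, since the ratio was 0.853 with summit and flank outside it (exact McNemar test, p = 3.68e-07). Against GC-matched flanks it was 0.963 (exact p = 0.2), since the share of flanks with the word fell from 41.8% to 35.5%, and 0.943 with both windows also outside coding sequence (exact p = 0.0418), so the low GC content of summits may account for most of the shortfall, and whether it accounts for all of it stays open. Whether weak peaks dilute an E-box signal stays open, since the ratio in the strongest 1119 peaks was 1.05 against GC-matched flanks (exact p = 0.427), neither above nor below 1 by the test. No choice gave an excess of CANNTG that passed the test, and no biological explanation was tested, since the design holds 1 group.

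Ribosomal protein genes had the highest ratio of genes with a peak to those expected, 4.62. A capture of all active promoters alike is argued against by the proteasome genes, of which 18.8% had a peak (Fisher's exact test, p = 6.59e-10), and a single library as the source by the lower of both replicates' shares, 80.0%. The proteasome and ribosomal protein lists were not matched on expression, so capture that rises with promoter activity was not tested. The TCT word YCTTTYN, the start site word of ribosomal protein genes, was searched in 4 windows: misplaced by 1 bp on the plus strand at first, then on both strands, then at the exact start, all of which held it at 1 or 2 ribosomal protein genes, and last from 5 bp before to 10 bp after the start. In that last window 53 ribosomal protein genes had the word, and of 223 other genes with it 33.2% had a peak, against 23.0% expected (exact stratified test, p = 3.71e-04), where the earlier windows gave 16.7%, 31.6% and 12.5% of 6, 19 and 24 genes and did not pass. That p was not adjusted for the 4 windows tried. The word stood at 1.63% of other genes in the last window, and the share that chance would give was not determined. Whether a feature shared with genes that start at this word contributes therefore stays open. Among ribosomal protein genes 45 of 53 with the word and 24 of 32 without it had a peak.

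DRE words were 10.1 times as frequent at summits as in flanks, where they stood only 8 times, and 15.3 and 4.17 times in the own lists of replicates 2 and 3. Base composition alone does not account for all of this, since the ratio fell but stayed at 4.26 against GC-matched flanks (exact p = 1.66e-10). In the strongest 1119 peaks that ratio was 1.71 (exact p = 0.359). Promoter sequence in general gave a lower share. DRE stood at 3.54% of promoter summits and at 1.63% of positions at like distances from starts without a peak (ratio 2.17, Fisher's exact test, p = 1.02e-04). Those positions had 39.9% GC against 34.9% at the promoter summits, and the GC-matched flanks were not matched for being promoters. Whether base composition and promoter sequence together account for the DRE excess therefore stays open. Outside promoters the ratio against flanks 500 bp away was 1, with 0.214% of 2334 summits and of flanks (exact p = 1). So few words cannot exclude an excess there, so whether the signal is one of promoter summits alone stays open. The genes without a peak were not matched on expression, so a difference in activity between both sets of promoters stays open.

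The same set of promoters without a peak gave values for the other words. At promoter summits the Fox word (9.74% against 5.41%, ratio 1.80, Fisher's exact test, adjusted p = 3.70e-06), the Mef2 word (8.30% against 4.43%, adjusted p = 4.82e-06) and the homeodomain word (10.7% against 6.81%, adjusted p = 8.66e-05) were more frequent than at those promoters. The M1BP word (1.77% against 1.21%, adjusted exact p = 0.333) and the GATA word (15.4% against 14.9%, adjusted p = 0.825) did not pass the test, and CANNTG was rarer (32.2% against 39.0%, adjusted p = 4.26e-05). GC content was 34.9% at promoter summits and 39.9% at promoters without a peak.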
